A study of Homo sapiens with 12 samples.

How the data were processed

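Per the labels' protocols, strand-specific total RNA libraries were made from IMR5 cells in 4 groups of 3: DMSO, 100 nM selinexor for 24 h, control siRNA and XPO1 siRNA, the last 2 at 72 h. Groups and replicate numbers were taken from the sample titles. Per the submitters' processing notes, STAR 2.7.3a, Partek and DESeq2 were used with genome build hg19; the annotation, the counting options and the use of strand are not given in the sources used here. The deposited values are a signal, gene counts divided by a size factor per library, which the authors computed separately for the selinexor table (20029 genes) and the knockdown table (19610 genes); 18987 genes are in both. Tests were made within a table, or on differences formed within each. The knockdown samples carried a single siRNA against XPO1. That table held 3 further columns of per-sample values, named for XPO1 siRNA with another number and matching no sample used here. These were not used, and no second siRNA was analysed here. There, 25 gene symbols had been turned into dates and were restored from their coordinates.

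The depth of each library was estimated from the steps of its low values. Between 61.8% and 66.6% of values from 0.3 to 60 were whole multiples of a step per column within 0.02, where chance gives 4%, and the rest were fractional, so whole reads could not be recovered and no count model was fitted. The deposited values times the recovered size factor gave the estimated reads per library, from 26.9 to 55.8 M. Counting intervals are exact 95% intervals on rounded estimated reads and cover counting error only. The share of counts from RN7SL1 and RN7SL2, abundant RNAs of the signal recognition particle, was 9.40% to 9.72% with DMSO, 12.6% to 16.0% with selinexor and 10.8% to 13.1% in the knockdown table. Replicate pairs of a group differed by 3.13 to 67.5 chi-square units per gene, above the 1 that counting alone would give, so no library was counted as deposited more than once.

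Genes with a mean value of 10 or more over the 6 libraries of a table were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend) on log2(value + 1), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The design had the group as its only term. For the difference of the 2 effects, the 12 libraries were fitted together with 4 group means. Of 25 gene lists written before the data were examined, 24 had at least 5 tested genes. These were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. Some lists share members with others: 7 genes of the BCL2 family and caspases, and 4 each of p53 targets, NF-kB targets and immediate early genes. BTG2 is both a p53 target and an immediate early gene here, and BIRC5 is in the mitotic and BCL2 lists. Tables and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. GC content, transcript length and gene type came from GENCODE 29 by gene symbol, for 85.5% of genes tested with selinexor and 86.6% with knockdown, and no coordinates were taken from it.

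The steps were tested on simulated data with known changes, 200 genes in each comparison. In the selinexor setting (17410 genes) 80.6%, 95.5% and 100% of genes changed 1.5-fold, 2-fold and 4-fold were recovered, with 6 false calls among 17210 unchanged genes. In the knockdown setting (17309 genes) the shares were 85.1%, 97% and 100%, with 5 false calls of 17109. For the difference of effects (16661 genes) 89.1% of 129 genes differing 2-fold and 100% of 130 differing 4-fold were recovered, with 10 false calls of 16269. Each simulation drew genes independently with 1 dispersion for all (0.00691 for selinexor and 0.000589 for knockdown). It changed no genes of low value and gave no library a trend with GC content. The real tables had 8920 and 9603 called genes, so recovery and false calls in the real data may be worse.

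Genes were named by a rule written before the data were examined: XPO1, MYCN and 1 gene not reported here; the 8 largest rises and 8 largest falls per comparison among called genes with a mean of at least 100 in the higher group and no overlap of libraries, passing over clone or locus numbers and small RNA genes; up to 4 called members of each list with the smallest p, or up to 2 where none was called; and between comparisons 5 genes per direction called in both with the same sign and 5 with opposite signs. Named after their values were seen were CDH5, KDR, ENG, CD74, MALAT1, NEAT1, RN7SK, 7SK, RN7SL1 and RN7SL2. Alternatives written beforehand were pseudocounts of 0.5 and 5, no filter, a mean of 50 or more, libraries rescaled to equal totals or by a 30% trimmed mean, each replicate left out, a replicate block, no trend, and a minimum log2 fold change of 1. Added after the data were seen were removal of each library's trend with GC content or transcript length, and voom on the estimated reads.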

Results

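RNA was sequenced from IMR5, an established human neuroblastoma cell line that carries amplification of the oncogene MYCN. Cells were grown with 100 nM selinexor, a small molecule inhibitor of the nuclear export receptor XPO1, for 24 h or with its solvent DMSO. The labels do not say how long the DMSO cells were grown. Other cells were nucleofected with a single siRNA against XPO1 or with control siRNA, and their RNA was taken after 72 h. Each of the 4 groups held 3 libraries. Estimated depth was 39.5 to 40.9 M reads per DMSO library, 26.9 to 33.8 M per selinexor library, 40.6 to 54.0 M per control siRNA library and 33.5 to 55.8 M per XPO1 siRNA library. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Values are the authors' normalized read counts, given as mean ± SD (n = 3), and fold changes are on the log2(value + 1) scale, which understates the change of low genes.

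The first comparison asked what selinexor did to the transcriptome. CDKN1A, which encodes the cell cycle inhibitor p21 (hg19 chromosome 6, 36644305 to 36655117), rose from 633 ± 33.2 to 27370 ± 1930, a log2 fold change of 5.43 (SE 0.0855). The replication licensing gene CDC6 fell 6.64-fold, from 3751 ± 112 to 565 ± 33.0. Of 33 tested p53 targets, 31 rose and 1 fell, and each of the 47 genes of DNA replication and the G1/S transition and of the 50 genes of G2/M and mitosis fell. In all, 4146 genes were higher and 4774 lower among 18128 tested (limma, Benjamini-Hochberg adjusted p under 0.05). The majority turned with libraries rescaled to equal totals, to 4644 higher and 4175 lower (52.7% higher in place of 46.5%). Changes of at least 1 on the log2 scale made up 1740 of the rises and 1002 of the falls. Without selinexor replicate 1, which stood apart, 5048 were higher and 6065 lower. The libraries of the groups did not overlap for 61.7% of genes, where chance gives 10%.

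The transcript of XPO1 itself (chromosome 2, 61704984 to 61765762) was not past the threshold with selinexor. It stood at 18380 ± 507 with DMSO and 19741 ± 3700 with selinexor, a log2 fold change of 0.09 (SE 0.135, limma adjusted p = 0.623). The selinexor libraries read 15544, 22513 and 21165, and without replicate 1 the log2 fold change was 0.25 (adjusted p = 0.00112, within a range of 0.000996 to 0.914 over all alternatives). Selinexor replicate 1 stood apart from the others, with a log2 correlation of 0.974 and 0.977 to replicates 2 and 3, which correlated at 0.991. The RNAs of the signal recognition particle, RN7SL1 and RN7SL2, took 9.40% to 9.72% of the counts with DMSO and 12.6%, 16.0% and 14.1% in the selinexor libraries. MYCN (chromosome 2, 16080686 to 16087130) gave a log2 fold change of 0.09 (SE 0.0976, adjusted p = 0.479), which was -0.0033 without selinexor replicate 1.

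**Figure D1:**
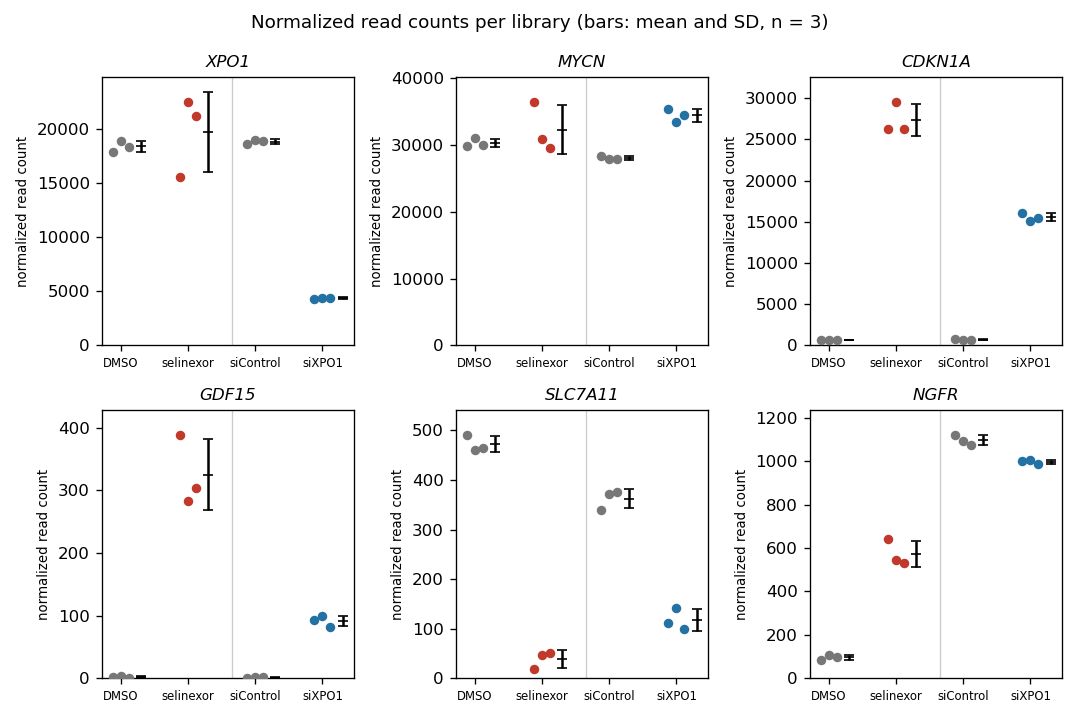
Normalized read counts (linear axis from 0) of 6 genes in each library of the DMSO, selinexor, control siRNA and XPO1 siRNA groups, with mean and SD beside the points (n = 3). The XPO1 siRNA libraries lie at about 4344 for XPO1 against 18809 in their controls, and CDKN1A is higher in each treated library than in each control; the selinexor and siRNA values come from tables normalized separately.

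Among genes with a mean of at least 100 in the higher group, no overlap of libraries and more than a clone number as a name, the largest rises were those of CYP4F3, GDF15, EPPK1, PVRL4, ATP8B4, PDE4C, ABCA12 and MUC19. CYP4F3, a fatty acid hydroxylase, went from 0.587 ± 0.509 to 379 ± 57.9. Its control libraries held about 2 reads in all against 1028, a ratio of 649 (95% exact counting interval 179 to 5370, counting error only). CYP4F3 has close paralogs with which reads may have been shared. The stress cytokine GDF15 went from 2.63 ± 1.76 to 325 ± 56.4. The largest falls were those of the cystine transporter gene SLC7A11 (472.7 ± 16.6 to 38.6 ± 17.9), the E2F family members E2F2 and E2F8, and the histone genes HIST1H2BM, HIST3H2BA, HIST1H3J, HIST1H2BH and HIST1H2BO. Histone genes are near-identical copies, and reads may have been split between them, so single members are uncertain.

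Among p53 targets, PHLDA3 rose 11.4-fold, BTG2 8.19-fold and CYFIP2 5.40-fold, and the list's median log2 fold change was 2.05 (camera adjusted p = 5.24e-20; adjusted p = 0.0822 with an estimated correlation). In the replication list, with a median of -1.99, E2F2 fell 9.72-fold, MCM4 5.35-fold and ORC1 5.47-fold (adjusted p = 0.059 with an estimated correlation). The mitotic list had a median of -1.74, and AURKB fell 4.98-fold, CDCA5 5.79-fold and MYBL2 6.63-fold (adjusted p = 0.0822 with an estimated correlation). All 22 tested replication-dependent histone genes fell, with a median of -2.46, among them HIST1H3B and HIST1H2AG (adjusted p = 0.162 with an estimated correlation). Of 33 genes of homologous recombination and Fanconi repair, 31 fell, including EXO1 by 7.08-fold (adjusted p = 0.179 with an estimated correlation). With the preset correlation, camera's adjusted p for these lists ran from 3.62e-29 to 2.97e-15.

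Genes of nuclear transport were lower in 47 of 58 cases and higher in 2, with RCC1 down 3.00-fold, RANBP1 2.35-fold and the importin gene KPNB1 2.03-fold (adjusted p = 0.179 with an estimated correlation). Of 47 MYC targets and ribosome biogenesis genes, 38 fell and 1 rose, among them UTP20, NOP56 and HSPD1 (adjusted p = 0.179 with an estimated correlation). All 31 proteasome genes fell, PSMD11 2.24-fold and PSMD7 1.91-fold (adjusted p = 0.213 with an estimated correlation). Cholesterol synthesis genes fell in 20 of 24 cases and rose in 2: SQLE fell 2.54-fold, while TM7SF2 rose 3.33-fold (adjusted p = 0.179 with an estimated correlation). Of 20 heat shock genes, 16 fell, including HSPA8 and HSPH1, and HSPA4L rose 6.34-fold (adjusted p = 0.179 with an estimated correlation). In the list of ATF4 targets and the unfolded protein response, 20 of 36 genes fell and 5 rose. The serine synthesis genes PHGDH and PSAT1 fell 4.15-fold and 3.04-fold (adjusted p = 0.186 with an estimated correlation). With the preset correlation, the adjusted p of these lists ran from 3.48e-12 to 0.000167.

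Of 27 immediate early genes, 18 rose and 1 fell, with ARC up 17.9-fold, EGR1 14.9-fold and FOS 9.13-fold (adjusted p = 0.059 with an estimated correlation). FOXO targets rose in 13 of 20 cases and fell in 5, FBXO32 5.61-fold up (adjusted p = 0.179 with an estimated correlation). Of 37 neuronal differentiation genes, 17 rose and 7 fell, with the microtubule gene DCX up 2.22-fold (adjusted p = 0.179 with an estimated correlation). Of 25 adrenergic neuroblastoma core factors, 12 rose and 3 fell, ISL1 1.90-fold and GATA3 1.88-fold up (camera adjusted p = 0.0342; adjusted p = 0.199 with an estimated correlation). That call was lost without DMSO replicate 1 (adjusted p = 0.0563) or DMSO replicate 3 (adjusted p = 0.0536), with the GC trend removed (0.119) and with no intensity trend (0.0573). Of 13 mitochondrially encoded genes, 8 rose, MT-ND5 3.22-fold (adjusted p = 0.557 with an estimated correlation and 0.154 by fry). Against the DMSO mean their median was 0.18 in selinexor replicate 1, 1.38 in replicate 2 and 1.54 in replicate 3. With the preset correlation, the adjusted p of these lists ran from 2.9e-07 to 0.0342.

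Lists not past the threshold held genes that moved both ways. In the BCL2 family and caspases (7 higher, 11 lower of 24, camera adjusted p = 0.392), BBC3 and BAX, which encode promoters of apoptosis, rose 24.4-fold and 2.64-fold while the survivin gene BIRC5 fell 3.31-fold; the list's median of -0.28 and mean of 0.0092 differed in sign. The counts higher and lower were 9 and 6 of 21 interferon-stimulated genes (PARP9 up, IFI44L down, camera adjusted p = 0.395), 5 and 3 of 15 NF-kB targets (RELB up, SOD2 down, 0.444) and 7 and 15 of 30 glycolysis and hypoxia genes (NDRG1 up, LDHA down, 0.136). They were 6 and 11 of 30 mesenchymal neuroblastoma markers (NOTCH1 up, YAP1 down, 0.415) and 3 and 2 of 8 Schwann and glial cell markers (ERBB3 up, CNP down, 0.392). Autophagy and lysosome genes (11 higher, 5 lower of 33, CTSL up 3.44-fold) and cytosolic ribosomal proteins (4 higher, 1 lower of 64, RPS19 up 1.77-fold) did not pass (camera adjusted p = 0.115 and 0.194). Both passed without selinexor replicate 1 (0.0256 and 0.000921), with equal totals (0.0373 and 0.0144), at a mean of 50 or more (0.0317 and 0.0386) and with length removed (0.0198 and 0.0109), and ribosomal proteins also with GC removed (0.0345). The test fry asks whether a list's genes move on balance one way and does not compare them with other genes. By fry, NF-kB targets (adjusted p = 0.0401), interferon-stimulated genes (0.0285), glycolysis (0.0136), mesenchymal markers (0.00198), Schwann and glial markers (0.00734) and autophagy genes (0.0267) passed. Fewer than 5 leukocyte and endothelial markers were tested, so that list has no test, and its members are named here after their values were seen. CDH5, an endothelial cadherin gene, rose by 1.04 on the log2 scale with selinexor (limma adjusted p = 0.00365) and by 1.17 with knockdown (6.08e-05). KDR, ENG and CD74 with selinexor (0.239, 0.0828 and 0.335) and KDR with knockdown (0.227) did not pass.

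Camera with its preset correlation called 16 of 24 lists, of which 0 held with an estimated correlation (6 at an unadjusted p under 0.05), and fry called 21. The correlation is estimated from the spread within groups, to which selinexor replicate 1 adds. For p53 targets it was 0.175 with selinexor and 0.015 with knockdown, while for glycolysis and hypoxia it was 0.111 and 0.507. These adjusted p-values therefore do not rank the evidence of the 2 comparisons. Other splits of the 6 libraries called 11 to 16 lists while limma called 0 genes. Each of these mixed treated and control libraries on both sides and so kept part of the treatment effect. They do not show what camera calls without a change. The counts of member genes carry the account above, to be read beside the 49.2% of all tested genes called. Lists that share members are not separate evidence. Adjusted over the list alone, the counts were as given except for nuclear transport (48 lower), MYC targets (39 lower), ATF4 (21 lower), the BCL2 family (12 lower), glycolysis (16 lower), adrenergic factors (6 lower), neuronal differentiation (18 higher), immediate early genes (19 higher) and ribosomal proteins (2 higher, 0 lower).

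The second comparison asked what loss of the XPO1 transcript did. XPO1 read 18568, 18950 and 18908 in the control siRNA libraries and 4260, 4377 and 4397 in the XPO1 siRNA libraries, a 4.33-fold fall (log2 fold change -2.11, SE 0.0311, limma adjusted p = 2.91e-14). CDKN1A rose from 688 ± 28.5 to 15550 ± 470, a log2 fold change of 4.50 (SE 0.0407). Of 33 p53 targets 31 rose, while all 22 replication-dependent histone genes, 45 of 47 replication genes and 46 of 50 mitotic genes fell. MYCN rose from 28040 ± 309 to 34440 ± 978 (log2 fold change 0.30, SE 0.0328). Among 17616 genes tested, 4561 were higher and 5042 lower, and 581 and 270 of these changed by at least 1 on the log2 scale. With libraries rescaled to equal totals the split was 6057 higher and 3647 lower, 62.4% higher in place of 47.5%. The comparison rests on a single siRNA, so effects of its sequence on other transcripts were not separated from those of the fall in XPO1.

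Under the same limits, the largest rises were those of CYP4F3, PVRL4, FRMPD2, INPP5D, CDKN1A, ACTA2, MUC19 and SLC16A6. CYP4F3 went from 0.354 ± 0.613 to 215 ± 25.6, about 1 read in all against 724, a ratio of 678 (95% exact counting interval 121 to 26800, counting error only). INPP5D, which encodes an inositol phosphatase, rose 33.4-fold and the smooth muscle actin gene ACTA2 12.4-fold. After XPO1 the largest falls were those of HIST3H2BA (3.94-fold), the ephrin receptor gene EPHA5 (3.67-fold), the interferon-stimulated gene IFI44L (3.65-fold), HIST1H2AD, HIST2H3D, SHISA3 and HIST1H3J.

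The p53 target list had a median log2 fold change of 1.26, with TP53INP1 up 4.58-fold, TNFRSF10B 2.80-fold and MDM2, which encodes a ubiquitin ligase, 2.40-fold. Replication genes had a median of -0.48, and MCM6 fell 1.82-fold and GINS2 2.03-fold. Mitotic genes had a median of -0.49, and CCNA2 fell 1.75-fold and AURKB 1.83-fold. In the list of ATF4 targets and the unfolded protein response, 26 of 36 genes fell and 3 rose, PHGDH 1.92-fold and ASNS 1.70-fold down. With an estimated correlation these 4 lists held, at adjusted p = 0.0153 for p53 targets and 0.0491 for each of the others; with the preset correlation the adjusted p of the lists here ran from 3.22e-23 to 5.16e-07. Histone genes had a median of -1.31, HIST1H1B 2.92-fold down (adjusted p = 0.0847 with an estimated correlation). Of 33 homologous recombination and Fanconi genes, 26 fell and 1 rose, EXO1 1.68-fold down (adjusted p = 0.0847 with an estimated correlation).

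Proteasome genes fell in 30 of 31 cases, PSMB3 1.49-fold (adjusted p = 0.0847 with an estimated correlation), and cholesterol synthesis genes in 22 of 25 with 2 higher, FDFT1 2.10-fold down (adjusted p = 0.0802 with an estimated correlation). In nuclear transport 43 of 58 genes fell, XPO1 among them, and 7 rose, with the importin genes KPNA2 and IPO5 1.56-fold and 1.44-fold down (adjusted p = 0.116 with an estimated correlation). Glycolysis and hypoxia genes fell in 23 of 31 cases and rose in 3, LDHA 1.93-fold down (adjusted p = 0.356 with an estimated correlation). Of 47 MYC targets and ribosome biogenesis genes 26 fell and 2 rose, with NPM3 2.27-fold down and ODC1, the polyamine synthesis gene, 2.02-fold up (adjusted p = 0.356 with an estimated correlation). Cytosolic ribosomal proteins fell in 26 and rose in 6 of 64 cases, RPL12 down and RPS19 up, with a median of -0.06 (camera adjusted p = 0.0226; adjusted p = 0.676 with an estimated correlation). With equal totals that median was 0.0276 (adjusted p = 0.815), and with length removed 0.0315 (0.444). The call was also lost without control siRNA replicate 2 (0.122) or XPO1 siRNA replicate 2 (0.0691), with GC removed (0.096), at a mean of 50 or more (0.073) and by fry (0.0692). The other lists of nuclear transport, metabolism and the proteasome had a preset-correlation adjusted p of 4.92e-12 to 0.00015.

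All 13 mitochondrially encoded genes rose, MT-ND5 1.95-fold (adjusted p = 0.216 with an estimated correlation). Adrenergic core factors rose in 15 of 25 cases with none lower, ISL1 2.19-fold and TBX2 1.95-fold (adjusted p = 0.127 with an estimated correlation). Of 37 neuronal differentiation genes 24 rose and 5 fell, CHGA 1.89-fold and DCX 1.69-fold up (adjusted p = 0.215 with an estimated correlation). Of 25 immediate early genes 10 rose and 3 fell, with BTG2 2.99-fold and DUSP6 3.13-fold up (adjusted p = 0.356 with an estimated correlation). With the preset correlation, the adjusted p of these 4 lists ran from 1.5e-08 to 0.00502. Not past the threshold were FOXO targets (9 higher, 5 lower of 20, TXNIP up; camera adjusted p = 0.0525), heat shock genes (6 and 13 of 20, HSPA4L 3.50-fold up, 0.155), mesenchymal markers (5 and 13 of 29, VIM down, 0.183), NF-kB targets (3 and 6 of 16, NFKBIA up, 0.458), interferon-stimulated genes (8 and 6 of 22, HERC5 up, 0.552) and Schwann and glial markers (2 and 2 of 6, PMP22 down, 0.9999). Falls within these lists included SOD2 (1.37-fold, NF-kB targets), IFI44L (3.65-fold, interferon-stimulated genes) and HSPB1 (1.48-fold, heat shock genes). FOXO targets passed without control siRNA replicate 1 (0.0357), control siRNA replicate 2 (0.0377) or XPO1 siRNA replicate 3 (0.049), at a mean of 50 or more (0.0232) and with voom (0.0481). Autophagy and lysosome genes (12 higher, 9 lower of 33, CTSL up 2.16-fold) had a median of -0.0066 and a mean of 0.057, and the BCL2 family (7 and 8 of 24, BBC3 up 7.02-fold and BAX 2.24-fold) had a median of 0.0087 with a test directed downward; neither passed (camera adjusted p = 0.444 and 0.9999). By fry, FOXO targets (adjusted p = 0.00085), NF-kB targets (0.0134), mesenchymal markers (0.0264) and autophagy genes (0.00895) passed.

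Camera called 16 of 24 lists here too and fry 19, and other splits of the 6 libraries called 11 to 16 lists while limma called 0 genes. These splits also mixed treated and control libraries, so they do not show what camera calls without a change. Of all tested genes, 54.5% were called in this comparison. Adjusted over the list alone, the counts were as given except for homologous recombination (2 higher), nuclear transport (9 higher), ribosomal proteins (22 lower), NF-kB targets (4 higher, 7 lower), FOXO targets (10 higher), autophagy (10 lower), glycolysis (4 higher) and mesenchymal markers (6 higher).

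**Figure D2:**
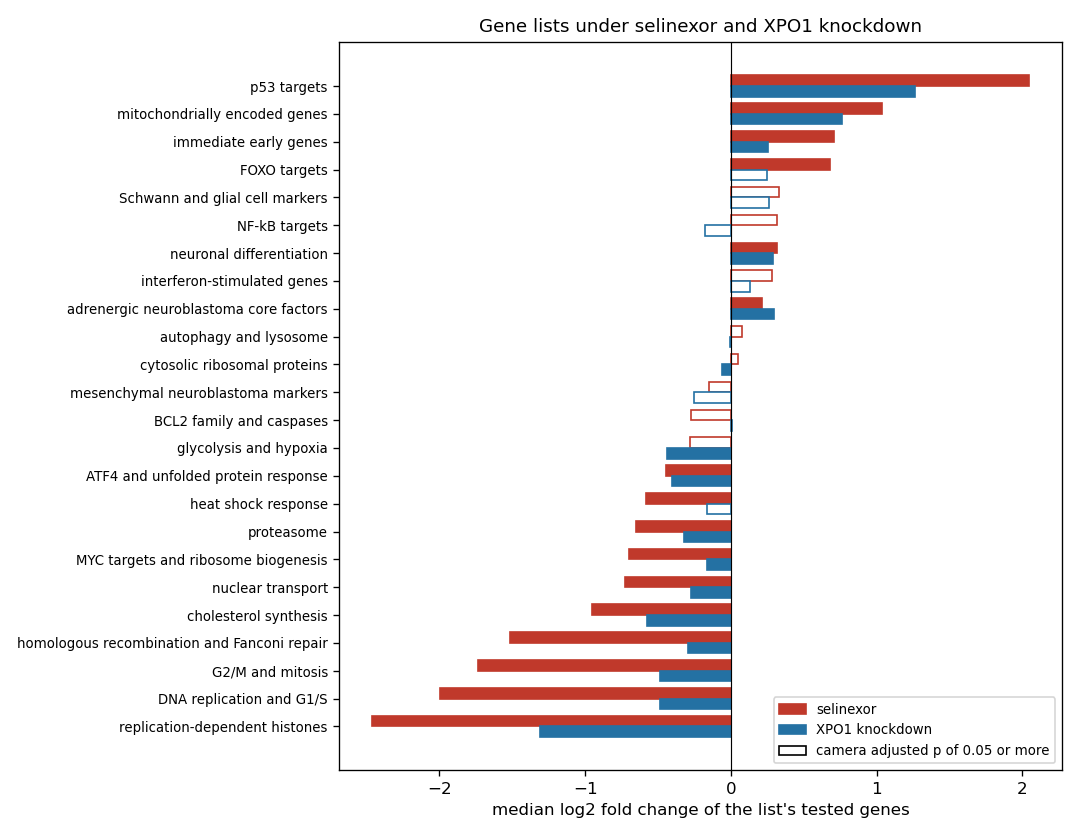
Median log2 fold change of the tested genes of each list under selinexor (red) and XPO1 knockdown (blue), with open bars where camera gave an adjusted p of 0.05 or more. The p53 targets have the largest positive medians (2.05 and 1.26) and the replication-dependent histones the largest negative ones (-2.46 and -1.31); with libraries rescaled to equal totals, the knockdown medians of ribosomal proteins and of autophagy and lysosome genes changed sign.

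The design also sets the drug beside the knockdown. Among genes with a mean of at least 100 in the higher group of each comparison, and ranked by the smaller of the 2 changes, CYP4F3, PVRL4, FRMPD2, INPP5D and CDKN1A led those higher in both. HIST3H2BA, IFI44L, HIST1H2AD, HIST2H3D and SHISA3 led those lower in both. GDF15, at 91.4 ± 8.54 with knockdown, fell under this minimum, with log2 fold changes of 6.60 and 5.52. FRMPD2 rose 45.7-fold with selinexor and 41.7-fold with knockdown, and IFI44L fell 3.42-fold and 3.65-fold. Among 17332 genes tested in both, 2252 were higher in both and 3176 lower in both, where independent lists would share 1034 and 1372. Another 167 were higher with selinexor and lower with knockdown, and 274 the reverse, where independent lists would share 1137 and 1248. This total of 441 was 732 without selinexor replicate 1, 273, 248 and 242 without DMSO replicates 1, 2 and 3, and 271 with no intensity trend. With libraries rescaled to equal totals, 2860 were higher and 2335 lower in both (55.1% higher in place of 41.5%), and 119 and 434 had opposite directions. Across genes, which are not independent replicates, the log2 fold changes correlated at Spearman's rho 0.607 and Pearson's r 0.643. No control library was shared.

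Under the same minimum, ranked by the difference of the effects and passing over genes with only a clone number, opposite directions were led by NGFR, RGS4, FMNL1, POU3F1 and SPRY1, higher with selinexor and lower with knockdown, and by CENPE, RCBTB2, CENPF, CKM and PROM1, lower with selinexor and higher with knockdown. The neurotrophin receptor gene NGFR rose 5.83-fold with selinexor, from 97.6 ± 11.8 to 574 ± 59.7, and went from 1097 ± 24.1 to 996 ± 9.13 with knockdown. The kinetochore gene CENPE fell 2.65-fold with selinexor and rose 1.26-fold with knockdown. Control siRNA values stood above DMSO values for each gene of the first group, as for RGS4 at 3886 ± 1680 against 109 ± 25.4. They stood below DMSO values for each gene of the second group, as for CENPE at 3036 against 5975. With knockdown RGS4 stood at 2084 ± 430. The libraries of the siRNA groups overlapped for RGS4 and CENPF. The 2 tables were normalized separately. Opposite responses to drug and knockdown thus cannot be told apart from this difference in the starting level of the controls. The knockdown call of NGFR was lost without control siRNA replicate 1 (adjusted p = 0.0614) or XPO1 siRNA replicate 3 (0.0647) and with equal totals (0.387). That of CENPF was lost without control siRNA replicate 1 (0.0643) or XPO1 siRNA replicates 2 (0.0584) or 3 (0.0533) and with the trend on transcript length removed (0.235). With no intensity trend the knockdown calls of RGS4 (0.0885), CENPE (0.0665) and CENPF (0.128) were lost. The selinexor call of RCBTB2 was lost without DMSO replicates 1 (0.0914), 2 (0.105) or 3 (0.0691) or selinexor replicate 3 (0.0682), with length removed (0.0504) and with no intensity trend (0.0624).

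**Figure D3:**
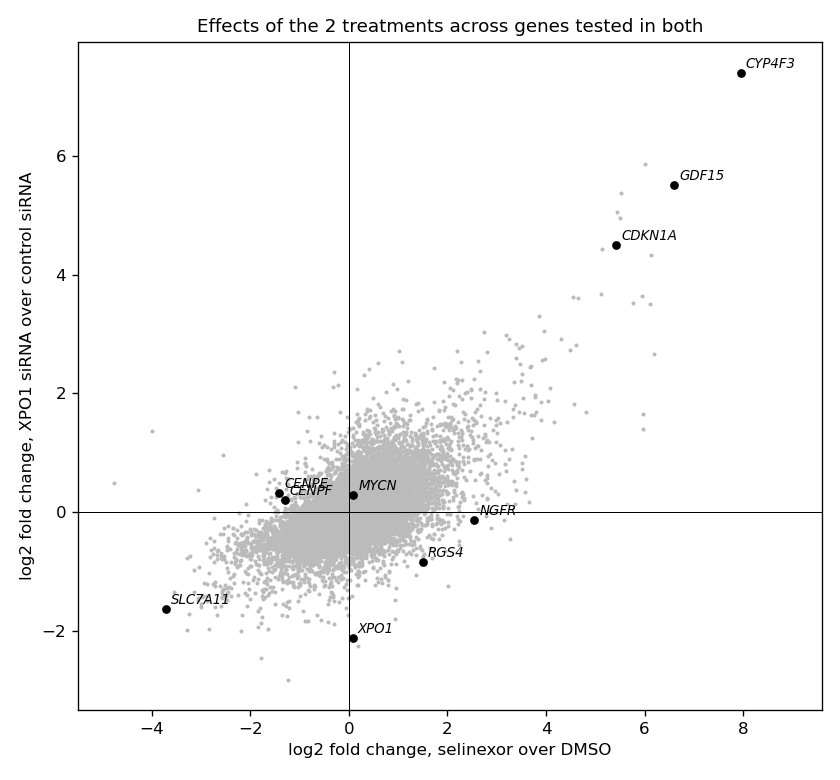
Log2 fold change with selinexor (x axis) against that with XPO1 knockdown (y axis) for the 17332 genes tested in both, with 10 genes labelled. CDKN1A, GDF15 and CYP4F3 lie at the upper right, and XPO1 lies at 0.09 and -2.11.

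The 2 effects differed for 5519 genes (limma on the 12 libraries, adjusted p under 0.05), with the selinexor effect above that of knockdown for 2014 and below it for 3505. The falls of replication and mitotic genes were deeper with selinexor, by a median of -1.47 and -1.31 on the log2 scale, and the rise of p53 targets was larger by 0.65 (camera adjusted p = 2.04e-39, 1.43e-34 and 1.94e-13; 0.00379, 0.0126 and 0.0467 with an estimated correlation). Exposure lasted 24 h for the drug and 72 h for the siRNA, and the controls and the tables' normalization differed, so the size of effects is confounded with these.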

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

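The tests of selinexor replicate 1, and those of CENPE and CENPF taken singly, were chosen after those results were seen. Effects of the drug and of the knockdown differed for 5519 genes by the test of the difference, given here as selinexor minus knockdown on the log2 scale. Drug and siRNA differ in duration, controls and normalization, and the knockdown rests on a single siRNA, so none of these differences is tied to XPO1 alone. The difference was 2.2 for XPO1, while that of MYCN did not pass. Genes higher with selinexor and lower with knockdown gave 2.68 for NGFR, 2.33 for RGS4, 2 for FMNL1, 1.94 for POU3F1 and 1.85 for SPRY1. Genes with the reverse gave -1.74 for CENPE, -1.64 for RCBTB2, -1.51 for CENPF, -1.41 for CKM and -1.39 for PROM1. Median differences of lists past camera's threshold were 0.65 for p53 targets, -1.47 for DNA replication and G1/S, -1.31 for G2/M and mitosis, -1.03 for homologous recombination and Fanconi repair, -1.12 for replication-dependent histones and -0.44 for nuclear transport. They were -0.43 for MYC targets and ribosome biogenesis, 0.13 for cytosolic ribosomal proteins, -0.66 for heat shock genes, -0.37 for the proteasome, 0.45 for FOXO targets, 0.13 for glycolysis and hypoxia and 0.54 for immediate early genes. With an estimated correlation, those of p53 targets, replication, mitosis, homologous recombination and immediate early genes passed.

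In 7 of 100 drawn splits of both tables, the real one included, as many genes differed as the real 5519, and the highest other split gave 10764. Of the 6 others, 1 kept both real groupings with one reversed and 5 kept the selinexor grouping. They carry that structure of the samples and are no reference without a change, so these splits do not decide whether chance is excluded for this count. The 80 drawn splits that kept neither grouping gave at most 0 genes with limma. They mixed treated and control libraries on both sides, which puts treatment differences into the spread within groups. They are therefore no reference without a change either. For genes called in both with the same sign, 1 of 100 splits, the real one with 5428, reached that number. The highest other gave 441, the number with opposite signs in the real groupings. Since other splits of either table called 0 genes, splits that broke a grouping had none to share, so this count of splits does not test the overlap either. With 3 against 3 there are 10 splits, too few for a share under 0.05. The real splits gave 8920 genes for selinexor and 9603 for knockdown, and the highest of the others 0 in both. In each, 1 split of 10 reached the real number. The others also mixed treated and control libraries, so their 0 does not show what limma calls without a change. For lists, 2 of 10 splits with selinexor and 3 of 10 with knockdown called as many as the real 16, and the highest other also called 16. The mixed splits keep part of the treatment effect, so these list counts are no reference without a change.

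Selinexor replicate 1 stood apart from replicates 2 and 3. Lower depth is argued against. With all 12 libraries thinned at random to its estimated reads, the smallest SD of log2 differences in a pair with replicate 1 (0.585) was 1.42 times the largest in the 10 other pairs within a group (0.411), with a range of 1.4 to 1.44 over 20 draws. The difference followed GC content over 13308 protein-coding genes (Spearman's rho 0.698, against -0.0984 to 0.0953 for each DMSO library and for replicate 2 against 3), consistent with a GC bias of that library. Whether that culture also responded more strongly stays open, since the slope of its effects on those of the others was 1.04 by least squares and 1.16 by the major axis, on different sides of the limit set.

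XPO1 was not past the threshold with selinexor. Once the GC trend of each library was removed, the SD of the selinexor libraries for XPO1, whose transcript has 37.9% GC, fell from 0.286 to 0.0602 on the log2 scale, a ratio of 0.21. The log2 fold change was then 0.35 (SE 0.0574, limma adjusted p = 0.000996), as a GC bias of replicate 1 hiding a higher XPO1 level would give. On the log2 scale replicate 1 went from 13.92 to 14.33. The removal also lowered the DMSO libraries, from 14.13, 14.21 and 14.16 to 14, 14.07 and 14.03. Part of the 0.35 thus does not come from replicate 1, and without that replicate the log2 fold change was 0.25. A real difference of the replicate 1 culture that follows GC content stays open.

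CENPE and CENPF were higher with knockdown while most mitotic genes were lower, and both have long transcripts. With the trend on transcript length removed, 1 of the 2 was still called. CENPE went from 0.33 (SE 0.08) to 0.231 (SE 0.075, adjusted p = 0.016), so the length trend is not the whole cause there. CENPF went from 0.21 (SE 0.065) to 0.0798 (SE 0.056, adjusted p = 0.23), the estimate having shrunk at a like error, so a length trend may account for it. For the pair together the length trend is not decided, and an effect of the knockdown remains among the open explanations.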

How the results depend on the processing

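The removal of GC and length trends and voom were chosen after seeing the data, as were MALAT1 and NEAT1 among the genes followed. Whole reads were not recovered, so the planned edgeR and DESeq2 fits were not run. Counts of called genes stayed within 1.5 times, at 6540 to 11113 for selinexor and 8428 to 9148 for knockdown with a replicate left out, except under a minimum log2 fold change of 1 (2742 and 851). At a mean of 50 or more, where fewer genes were tested, changes of at least 1 numbered 894 higher and 886 lower with selinexor and 229 and 156 with knockdown. XPO1 stayed lower with knockdown under each alternative run. With selinexor and a replicate left out, its log2 fold change ran from -0.0188 (without replicate 2) to 0.2484 (without replicate 1, past the threshold), and that of MYCN from -0.003317 (without selinexor replicate 1) to 0.1507. XPO1 was at 0.3466 with the GC trend removed. With an estimated correlation 0 lists were called for selinexor and 4 for knockdown, and by fry, which compares a list with no other genes, 21 and 19. Genes with differing effects ran from 4359 to 7634 with a replicate left out. The correlation of the effects was 0.577 with no filter, 0.655 at a mean of 50 or more and 0.574 to 0.625 with a replicate left out. Replicate numbers showed no clear pairing of the libraries (correlations of deviations 0.01, 0.12 and -0.04 for selinexor and -0.03, -0.02 and -0.1 for knockdown). Among the control libraries, only DMSO replicate 2 was closest to the treated library of its own number. With 3 libraries per group, and replicate 1 apart within selinexor, this cannot exclude a shared culture or batch. With the replicate block 8671 and 9321 genes were called, 5073 differed, 5220 were shared and rho was 0.607. FOXO targets then passed with knockdown (camera adjusted p = 0.0499). Of lists with knockdown that had not passed, the direction of the test turned for the BCL2 family and caspases (medians 0.00871 at a mean of 50 or more and with fry, 0.099 at equal totals, 0.0286 with GC and 0.00942 with length removed, -0.041 to 0.0132 with a replicate left out). It also turned for Schwann and glial markers (0.263 at pseudocount 0.5, 0.35 at equal totals, 0.265 by trimmed mean, 0.261 with the block and with fry, 0.268 with GC removed, 0.106 to 0.265 with a replicate left out). Ribosomal proteins, which had passed (camera adjusted p = 0.0226), turned with length removed (median 0.0315). Over all settings run for named genes and lists, 72 values lost the threshold with direction kept, 25 gained it so and 20 changed direction. Another 5038 were labelled the same, among them counts of genes higher and lower that stayed within 1.5 times. The cause was not tested.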

Other observations

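Gene types were compared after the data were seen, and MALAT1, NEAT1, RN7SK and 7SK were chosen then too. NEAT1, the nuclear RNA that builds paraspeckles, rose from 1241 ± 189 to 8240 ± 785 with selinexor (log2 fold change 2.74, SE 0.125) and from 979 ± 214 to 3605 ± 67.5 with knockdown (1.90, SE 0.105). MALAT1, a nuclear speckle RNA, rose by 1.23 (SE 0.126) with selinexor and 1.54 (SE 0.0732) with knockdown. Both were higher in 3 of 3 treated libraries than in any control, and stayed called under each alternative run. The small nuclear RNA RN7SK was not past the threshold in either comparison (limma adjusted p = 0.124 and 0.951).

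With selinexor, long intergenic RNAs had a median log2 fold change of 0.40 (75 higher, 9 lower of 208) and genes typed as antisense one of 0.44 (99 higher, 24 lower of 310), both past camera's threshold with an estimated correlation (adjusted p = 0.0145 each). Whether the counting used strand is not given in the sources used here, so antisense genes cannot be told from their partners. Small nuclear RNAs had a median of 0.97 (22 higher, 0 lower of 36) and small nucleolar RNAs one of 0.74 (41 higher, 0 lower of 75), with adjusted p = 0.346 and 0.258 with an estimated correlation. In the knockdown these medians were 0.25, 0.20, 0.01 and 0.17, and no type passed with an estimated correlation. With the preset correlation, long intergenic RNAs and antisense genes passed there (camera adjusted p = 0.00742 and 0.0405). Camera compared each type with all other tested genes, whatever their level. With selinexor 46.5% of called genes were higher among all tested and 39.8% at a mean of 50 or more. Whether these types rose more than genes of like level was not tested.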
